A study of Marchantia polymorpha with 15 samples.

How the data were processed

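RNA was measured in thalli, the flat vegetative body, of the liverwort Marchantia polymorpha. Per the labels, the plants were 1 month old, of the female accession Tak-2, untreated, and grown on solid medium under long days; libraries came from a stranded total RNA kit made for plants, from RNA above an integrity limit. The 15 libraries formed 5 groups of 3: wild type (WT), 2 independent lines with a knockout of MpVIH (Mpvih lines 1 and 2), and 2 independent lines that carry an artificial microRNA against MpDELLA in the Mpvih background (amiR-MpDELLA Mpvih lines 1 and 2). The series describes the replicates as biological; nothing says whether they came from separate cultures or days, so p-values measure the spread between these libraries. The labels do not say in which Mpvih line each amiR line was made, and lines were not paired. The titles of the WT libraries hold the word Gemma, and those of the Mpvih and amiR libraries do not. If it marks other starting material, that difference cannot be told apart from genotype in contrasts with WT.

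The deposited table holds estimated counts per gene (expected counts, not all whole) for 19073 gene IDs, with no scaling between libraries. Between 4.05% and 6.28% of the values in a library carried a fraction. FastQC, Trim Galore 0.6.6, Salmon 1.4.0 and DESeq2 1.36.0 are named in the submitters' processing notes, with no role or order. The genome build, the annotation and the way transcripts were summed to genes are not given in the sources used here, so no coordinates are printed and a chromosome is read only from the gene ID. Salmon divides reads that fit several transcripts between them by estimate, so values of near-identical neighbouring genes, such as members of a tandem family, are uncertain where they share sequence. Library totals ran from 9545653 to 16647506 counts. Replicate libraries of a group differed by more than sampling noise (lowest chi-square per degree of freedom 16.5), so they were not repeated sequencing of 1 library. That does not show that they came from separate plants. Each was counted as a sample because the series describes the replicates as biological.

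Gene names came from a reference table of the Tak-2 genome, version 7.1, which pairs locus tags with symbols and gives no protein products. Exchanging the locus tag's prefix for that of the table matched 17695 of the 19073 IDs (92.8%). As a check on the numbering, 311 of the 318 IDs whose number does not end in 0 were also in the reference, and 1265 of 1314 numbers skipped in the table were skipped in the reference as well. The reference names 86 genes, of which 85 were in the table and 73 were tested, so most genes have no name here. No source used here pairs an ID with MpVIH. For MpDELLA, the reference gives the symbol MpGRAS6 to the locus published under the name MpDELLA; that identity rests on published nomenclature, not on the reference.

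Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 5 groups, which left 12850. Libraries were scaled by TMM (trimmed mean of M values), and a quasi-likelihood model with robust estimation was fitted with 1 mean per group, so that all groups shared the estimate of the spread (common dispersion 0.118). Genotype contrasts averaged the 2 lines of a genotype. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Levels are given as CPM (the usual depth-scaled unit) computed with TMM-scaled library totals, as mean ± SD over the libraries of a genotype. Where all libraries of a genotype were at 0, a fold is a lower bound against a floor of 3 counts over the group. Intervals on shares of genes are 95% exact Clopper-Pearson intervals and treat genes as independent, which they are not. The procedure was tested on simulated counts for the 12850 genes in which 100 genes changed 2-fold and 100 changed 4-fold. In Mpvih against WT it recovered 35% and 78% of them with 1 false call, and in amiR-MpDELLA Mpvih against Mpvih 41% and 86% with 3 false calls. In all, 114 and 130 genes were called in the simulated contrasts, against 2446 and 4892 in the real ones. The same adjusted p was therefore a stricter cut in the simulation, and its shares do not carry over. Changes near 2-fold can be missed, but how often was not measured for the real contrasts.

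The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took the gene targeted in each genotype where an ID was paired with it. For Mpvih against WT and for amiR-MpDELLA Mpvih against Mpvih it took genes with a symbol that were called in the genotype contrast and in both single-line contrasts, with no overlap between the libraries of the genotypes and at least 5 CPM in the higher genotype, up to 10 higher and 10 lower by size of change. It also took up to 3 members of each gene list by adjusted p. Because the reference gives symbols only, most lists had no member by name: flavonoid, phosphate, inositol phosphate, redox, heat shock, desiccation, auxin, cell wall, cell cycle, photosynthesis, ribosome, polyphenol oxidase, P450, nitrate and sulphate, and defence. Members were found for terpene synthases, jasmonate, the gibberellin, DELLA and GRAS list, oil body cells, rhizoids, the gemma cup, sexual organs, and genes linked to the female (U) and male (V) sex chromosomes. Lists with at least 5 tested genes were tested with camera and fry in limma 3.58.1, camera with a preset correlation between genes of 0.01 and again with an estimated correlation. Beyond the rule, the other tested members of the terpene synthase list are also given. Remaining genes named outside the rule are marked in the text as chosen after their values were seen.

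Overlaps between contrasts that share libraries are given beside the overlap of independent lists and beside 20 simulated sets without effects. To read the genes of Mpvih in the amiR lines without reusing libraries, genes were chosen in Mpvih line 1 against WT and read in the amiR lines against Mpvih line 2, and the other way round. Alternatives were DESeq2 size factors, DESeq2 1.42.0 as the test, no or a stricter filter, a fold threshold, fits with only the compared groups, with 3 genotype means or with a replicate block, and leaving out each library. After the data were seen, 2 more were added: a term for the 4 libraries with a TMM factor below 0.9 (composition term), and a fit without them. That fit leaves amiR line 2 with replicate 1 alone. Figures were drawn with matplotlib 3.10.9.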

Results

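The series compared thalli of wild-type Marchantia polymorpha with plants lacking MpVIH, a kinase of the VIH type that makes inositol pyrophosphates, and with plants of that mutant background in which an artificial microRNA targets MpDELLA. DELLA proteins are growth regulators that gibberellin removes in vascular plants. The series' title asks how DELLA is regulated by VIH without gibberellin. There were 3 WT libraries, 6 Mpvih libraries from 2 lines and 6 amiR-MpDELLA Mpvih libraries from 2 lines. Totals lay between 9545653 and 16647506 counts per library, and 11807 to 12486 genes had at least 10 counts. On the first principal component, which held 47.5% of the variance, the 6 Mpvih libraries lay between 58.6 and 74.3, and the 9 WT and amiR-MpDELLA Mpvih libraries between -77.2 and -14.1. The second component (17.0%) parted 4 libraries from the other WT and amiR libraries: WT replicate 1, amiR line 1 replicate 1, and amiR line 2 replicates 2 and 3. These 4 also lay farthest from Mpvih on the first component, between -77.2 and -63, against -30.5 to -14.1 in the other WT and amiR libraries. Their TMM factors were 0.693 to 0.873, against 1.03 to 1.19 in the other 11 libraries, and their 50 most abundant genes took 18.8% to 24.1% of the counts, against 12.4% to 16.8%. By these 2 measures no Mpvih library was among them. On the second component Mpvih line 1 lay between 15.6 and 34.1, overlapping the 4 libraries (20.6 to 57.5), and Mpvih line 2 between -5.03 and 8.34.

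The transcript targeted by the artificial microRNA was read first. MpGRAS6 (Mp5g20660), the locus published as MpDELLA, stood at 20.5 ± 4.18 CPM in WT (SD, n = 3), 27.3 ± 3.93 CPM in Mpvih (n = 6) and 21.7 ± 3.89 CPM in amiR-MpDELLA Mpvih (n = 6). Its log2 difference between amiR-MpDELLA Mpvih and Mpvih was -0.33 (SE 0.16, adjusted p = 0.12), which did not pass the threshold, with a 95% interval from -0.67 to 0.01. With the composition term for the 4 libraries that stand apart, an alternative chosen after seeing the data, the difference was -0.29 with an adjusted p of 0.25. Without those libraries, also chosen after seeing the data, it was -0.49. There amiR line 2 is replicate 1 alone, which had the lowest level of the 6 amiR libraries (16.1 CPM). The left-out libraries of that line stood at 24.6 and 25 CPM, so nothing is concluded from that fit. Against WT the difference was 0.41 (SE 0.20, adjusted p = 0.16) in Mpvih and 0.09 in amiR-MpDELLA Mpvih. The MpVIH transcript was not analysed here, because no source used here pairs a gene ID with it, so the knockout was not checked at the RNA level.

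The comparison of Mpvih with WT asked what the loss of MpVIH changed. Among named genes, the R2R3-MYB transcription factor gene MpR2R3-MYB10 (Mp6g04830) fell from 47.5 ± 14.9 CPM in WT to 1.78 ± 1.54 CPM in Mpvih, 29.7-fold lower (log2 fold change -4.89, SE 0.34, adjusted p = 5.8e-06). MpLUX (Mp4g21220), whose namesake in flowering plants is a component of the circadian clock, fell from 148 ± 42.6 to 47.4 ± 6.92 CPM, 3.13-fold (-1.64, SE 0.19, adjusted p = 8.5e-05). MpSTOP2 (Mp8g12510) fell 2.05-fold, from 91.6 ± 5.93 to 45.8 ± 12.3 CPM, and MpZOU1 (Mp4g19650) fell 2.90-fold, from 5.64 ± 1.37 to 1.93 ± 0.373 CPM. MpB3-6 (Mp5g08310), named for a B3 DNA-binding domain, rose 3.09-fold, from 30.4 ± 13.3 to 94.6 ± 23.8 CPM (1.63, SE 0.35, adjusted p = 0.0060). MpSBG9 (Mp1g09420) rose 3.06-fold, from 24.7 ± 7.76 to 75.9 ± 16.9 CPM (1.61, SE 0.33, adjusted p = 0.0050). MpKCS3 (Mp2g20240), of the 3-ketoacyl-CoA synthase family that elongates very long chain fatty acids, rose 2.04-fold, from 82.9 ± 9.32 to 169 ± 24.8 CPM. MpCNL1 (Mp3g09150) rose 1.93-fold, from 5.42 ± 0.716 to 10.5 ± 1.76 CPM.

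Genes of the microbial-type terpene synthase family, enzymes of terpenoid synthesis, were lower in Mpvih. The table held 8 members, of which 7 were tested; 5 fell and 0 rose, with the same counts adjusted over the list alone. MpMTPSL15 (Mp6g04400) fell 25.4-fold, from 48.5 ± 19.7 CPM in WT to 2.07 ± 1.10 CPM in Mpvih (log2 fold change -4.67, SE 0.36, adjusted p = 6.8e-06). MpMTPSL7 (Mp6g04320) fell 4.19-fold, from 69.6 ± 19.3 to 18.3 ± 8.82 CPM (-2.07, SE 0.26, adjusted p = 0.00021). MpMTPSL13 (Mp6g04610) had 232 counts over the 3 WT libraries and 0 over the 6 Mpvih libraries, at least 148-fold lower in CPM. MpMTPSL11 (Mp6g04600) had 308 counts in WT and 6 in Mpvih, and MpMTPSL12 (Mp6g04580) had 29 and 3. MpMTPSL6 (log2 difference -1.5, adjusted p = 0.22) and MpMTPSL10 (-1.06, adjusted p = 0.40) did not pass. Camera placed the list below other genes with an adjusted p of 1.7e-05, and with adjusted p = 0.11 under an estimated correlation; fry's directional adjusted p was 6.6e-05. Several members lie next to each other by ID, so reads that fit more than 1 of them were divided by estimate. In the fit with the composition term, 4 members were higher in the 4 libraries that stand apart than in the others of their groups: MpMTPSL6 4.02-fold (adjusted p = 0.045), MpMTPSL12 3.54-fold (0.035), MpMTPSL15 2.05-fold (0.00044) and MpMTPSL7 1.65-fold (0.0048).

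Markers of cell types and structures had few named members. MpKARAPPO (Mp5g06550), which is required for gemmae to form in the gemma cup, rose 1.91-fold in Mpvih, from 22.8 ± 1.25 to 43.5 ± 8.32 CPM (log2 fold change 0.93, SE 0.16, adjusted p = 0.0018). The oil body list held MpMYB02 (Mp3g07510), a regulator of marchantin synthesis, which fell 1.93-fold, from 10.8 ± 0.995 to 5.59 ± 2.06 CPM (-0.95, adjusted p = 0.026). That call was lost without any single WT library, without Mpvih line 1 replicate 3 or line 2 replicate 1, and without the 4 libraries that stand apart (adjusted p from 0.056 to 0.089), where the difference still lay between -0.99 and -0.87. MpRSL1 (Mp3g17930), a rhizoid regulator, differed by 0.05 (adjusted p = 0.91). The allene oxide synthase genes of the jasmonate list were not called in Mpvih by edgeR over all genes: MpAOS1 differed by -0.68 (adjusted p = 0.057) and MpAOS2 by -0.45 (adjusted p = 0.23), with 1 of the 2 lower when adjusted over the list alone. MpAOS1 was called by DESeq2 (adjusted p = 0.034), in the fit of only the groups compared (0.0315) and without amiR line 2 replicate 1 (0.0231). MpBNB, a regulator of sexual organs, had 5 counts over all 15 libraries and was not tested.

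Over all 12850 tested genes, edgeR's quasi-likelihood test called 2446 (19.0%) in Mpvih against WT, 930 higher and 1516 lower, and 1525 of these changed at least 2-fold, 494 up and 1031 down. Of the 73 tested genes with a symbol, 6 rose and 14 fell. The count was 1577 without WT replicate 1, 1614 without WT replicate 2 and 1621 without WT replicate 3, so each of the 3 WT libraries carried weight.

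Single lines were compared with WT and with each other to ask whether independent knockout lines changed alike. Mpvih line 1 differed from WT in 1406 genes, 569 higher and 837 lower, and line 2 in 1886, 749 higher and 1137 lower. MpR2R3-MYB10 fell by 4.14 in line 1 and by 5.64 in line 2 on the log2 scale, and MpMTPSL15 fell by 4.05 and 5.28. Both lines shared 348 higher and 667 lower genes, 1015 in all, and 0 genes were called in opposite directions. Independent lists would share 33 and 74, and simulated lines without effects shared 0 at most. Fold changes of the lines correlated across genes with r = 0.836, against 0.498 in simulated lines that share the same WT libraries; the covariance was 1.28 against 0.124. With 3 WT libraries the controls could not be split with 2 in each part, so part of this excess may come from the shared WT libraries. Compared directly, line 2 against line 1, edgeR called 0 genes, with 970 at an unadjusted p under 0.05 where 642 are expected by chance. DESeq2 called 142, and the fit with the composition term 54. For MpR2R3-MYB10 the lines differed by -1.5 (adjusted p = 0.43), and for MpMTPSL7 by -1.28 (adjusted p = 0.29).

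**Figure D1:**
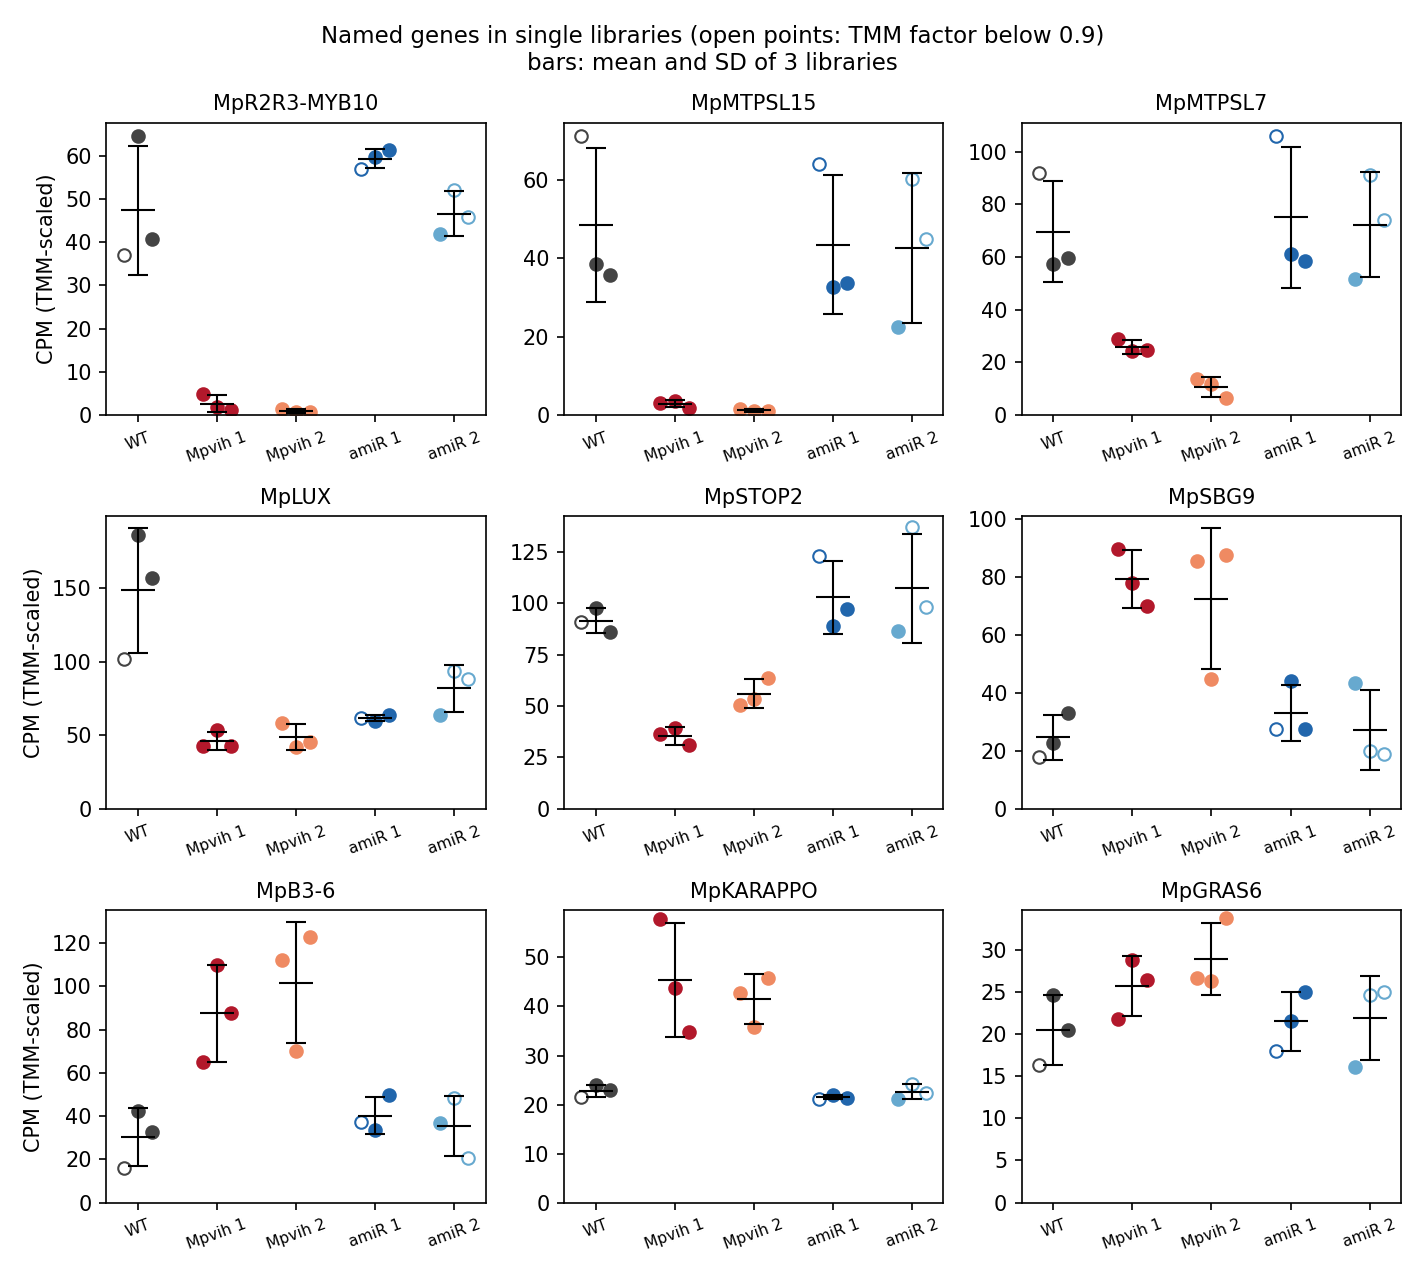
TMM-scaled CPM (vertical axes, from 0) of 9 named genes in the 3 libraries of each of the 5 groups (horizontal axes); points are libraries, bars the mean and SD of a group, and open points the 4 libraries with a TMM factor below 0.9. MpR2R3-MYB10 stood at 1.78 CPM over the 6 Mpvih libraries, against 47.5 in WT and 53.0 in amiR-MpDELLA Mpvih, while MpLUX stood at 71.7 CPM in amiR-MpDELLA Mpvih, between Mpvih (47.4) and WT (148).

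The comparison of amiR-MpDELLA Mpvih with Mpvih asked what targeting MpDELLA changed in plants without MpVIH. Several named genes that fell in Mpvih were higher again. MpR2R3-MYB10 rose 32.9-fold to 53.0 ± 7.84 CPM (log2 fold change 5.04, SE 0.32, adjusted p = 2.6e-06). MpSTOP2 rose 2.35-fold to 105 ± 20.1 CPM (1.24, SE 0.14, adjusted p = 4.3e-05), and MpZOU1 2.62-fold to 5.17 ± 1.96 CPM. MpMYB02 rose 1.93-fold to 10.8 ± 0.700 CPM (adjusted p = 0.0063), and by about as much on the log2 scale without the 4 libraries that stand apart (0.93 against 0.95), where the adjusted p on fewer libraries was 0.055. MpDLP (Mp7g12630) rose 1.49-fold, from 26.0 ± 3.43 to 38.6 ± 5.62 CPM, and MpKCS1 (Mp1g06080) 1.47-fold, from 47.2 ± 3.83 to 69.4 ± 13.3 CPM. Their falls in Mpvih were small, and leaving out 1 library ended the calls. The log2 differences changed little there: -0.46 and -0.52 for MpDLP, and -0.59 to -0.52 for MpKCS1. MpDLP fell by 0.54 (adjusted p = 0.019; 0.0832 without WT replicate 1 and 0.0668 without WT replicate 2). MpKCS1 fell by 0.56 (adjusted p = 0.023; 0.0518 to 0.0748 without WT replicate 1, 2 or 3, Mpvih line 1 replicate 3 or line 2 replicate 1). Genes that had risen in Mpvih fell: MpSBG9 2.52-fold to 30.2 ± 11 CPM, MpB3-6 2.50-fold to 37.8 ± 10.7 CPM, MpKARAPPO 1.97-fold to 22.1 ± 1.16 CPM (-0.98, SE 0.13, adjusted p = 0.00013) and MpKCS3 1.81-fold to 93.9 ± 21 CPM. MpPINTOX (Mp1g01010) fell 1.59-fold, from 26.4 ± 3.18 to 16.6 ± 2.30 CPM, and MpPLINC (Mp8g08190), of a zinc finger homeodomain family, 1.49-fold, from 279 ± 14.7 to 187 ± 36.8 CPM. In place of -0.58, the MpPLINC difference was -0.38 with the composition term (adjusted p = 0.02) and -0.36 without the 4 libraries. MpCNL1 differed by 0.03 (SE 0.16, adjusted p = 0.89) between the genotypes.

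All 7 tested terpene synthase genes rose in amiR-MpDELLA Mpvih against Mpvih, and 7 also rose when adjusted over the list alone. MpMTPSL15 rose 22.6-fold to 43.1 ± 16.6 CPM (log2 fold change 4.50, SE 0.34, adjusted p = 3.2e-06) and MpMTPSL7 4.44-fold to 73.7 ± 21.1 CPM (2.15, SE 0.23, adjusted p = 3.7e-05). MpMTPSL13 had 271 counts over the 6 libraries, at least 97.2-fold above the floor of Mpvih in CPM. MpMTPSL6 rose 8.54-fold to 38.2 ± 27.3 CPM (3.09, SE 0.76, adjusted p = 0.0072). Camera gave an adjusted p of 1.7e-05, and adjusted p = 0.11 with an estimated correlation; fry's directional adjusted p was 1.7e-05. With the composition term 4 of the 7 rose, and without the 4 libraries that stand apart 3 of the 6 then tested rose. MpMTPSL6 was not called in either: its log2 change of 3.09 was 1.84 with the composition term (adjusted p = 0.063) and 1.55 without the 4 libraries (0.20), while MpMTPSL7, MpMTPSL13 and MpMTPSL15 were called in both. In the jasmonate list MpAOS1 differed by 0.30 (adjusted p = 0.24) and MpAOS2 by 0.57 (adjusted p = 0.053), and 1 of the 2 was higher when adjusted over the list alone. MpAOS2 was 1.71-fold higher in the 4 libraries that stand apart, and its difference was 0.13 (adjusted p = 0.48) with the composition term and 0.09 (adjusted p = 0.67) without those libraries; that of MpAOS1 was -0.04 and -0.12. MpAOS2 was called by DESeq2 (0.59, adjusted p = 0.0255), with 3 genotype means (0.0483), and without WT replicate 1 (0.037), amiR line 1 replicate 3 (0.0398) or amiR line 2 replicate 1 (0.0136). MpRSL1 differed by -0.21 (adjusted p = 0.52).

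Over all genes, edgeR called 4892 (38.1%) between amiR-MpDELLA Mpvih and Mpvih, 2613 higher and 2279 lower, of which 2223 changed at least 2-fold. Among the genes with a symbol 19 rose and 17 fell, against 17 and 9 with the composition term and 14 and 11 without the 4 libraries that stand apart. Each amiR line against the mean of the Mpvih lines gave 2979 genes in line 1 and 3559 in line 2, with 2237 shared in direction, 1382 higher and 855 lower, where independent lists would share 289 and 138 and simulated lines 0. With the Mpvih lines split so that no library was used for both, 1129 genes were shared, 714 higher and 415 lower. Independent lists would share 129 and 72, and r across genes was 0.713 against 0.000941 in simulation. The simulation held no differences in composition between libraries. Libraries that stand apart lie in both amiR lines and in no Mpvih line, so part of the sharing may come from them. With the Mpvih lines not split, the count of 2237 shared genes was 2102 with the composition term. Without the 4 libraries that stand apart, amiR line 2 keeps only replicate 1, so nothing is concluded from the overlap in that fit. The count of shared genes was 1374 without amiR line 1 replicate 1 and 1410 without amiR line 2 replicate 2, both among those 4. Between amiR lines edgeR called 0 genes, with 436 at an unadjusted p under 0.05 where 642 are expected by chance, and DESeq2 called 4.

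Whether the genes changed in Mpvih moved back was read with separate Mpvih libraries. Of the 1406 genes called in Mpvih line 1 against WT, 1331 (94.7%, 95% interval 93.4% to 95.8%) had the opposite sign in amiR-MpDELLA Mpvih against Mpvih line 2. The 569 genes that rose in line 1 had a median log2 fold change of 1.61 there and of -1.05 in the amiR lines against line 2. The 837 that fell had medians of -1.72 and 1.5. Fry's directional p was 3.3e-07 for the first set and 7.7e-10 for the second. Chosen in line 2 and read against line 1, 97.3% of 1886 genes had the opposite sign. By calls, 2223 of the 2446 genes of Mpvih against WT were also called between amiR-MpDELLA Mpvih and Mpvih in the opposite direction and 2 in the same direction, although this count uses the same Mpvih libraries for both. A further 2667 genes were called between amiR-MpDELLA Mpvih and Mpvih and not between Mpvih and WT; a test of whether their changes differ was not made.

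**Figure D2:**
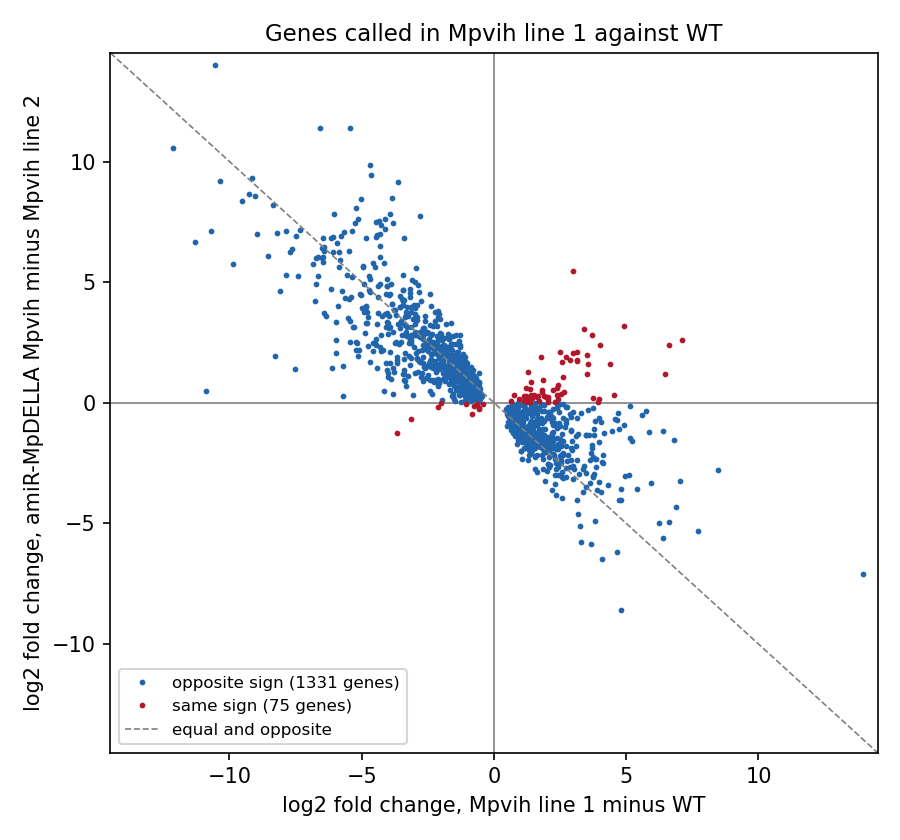
Each point is 1 of the 1406 genes called in Mpvih line 1 against WT; the horizontal axis is that log2 fold change and the vertical axis the log2 fold change of amiR-MpDELLA Mpvih against Mpvih line 2, with no library used on both axes. Blue points (1331) have opposite signs on the axes and red points (75) the same sign; the dashed line marks equal and opposite changes.

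The comparison of amiR-MpDELLA Mpvih with WT asked what still differed. Most named genes lay near their WT level: the log2 difference was 0.15 for MpR2R3-MYB10, -0.17 for MpMTPSL15, 0.08 for MpMTPSL7, -0.05 for MpKARAPPO and 0.17 for MpKCS3, all with an adjusted p of 1. MpLUX stayed lower, at 71.7 ± 14.9 against 148 ± 42.6 CPM (-1.06, SE 0.19), without passing the threshold (adjusted p = 0.12). Against Mpvih it had risen by 0.58 (adjusted p = 0.013). That rise was 0.63 with the composition term (adjusted p = 0.019) and 0.41 without the 4 libraries. MpCNL1 stayed higher, at 10.8 ± 1.57 against 5.42 ± 0.716 CPM (0.98, SE 0.21, adjusted p = 0.20). EdgeR called 5 genes, 5 higher and 0 lower, and 713 at an unadjusted p under 0.05 where 642 are expected by chance. Other settings gave other counts and directions: DESeq2 called 123, 95 higher and 28 lower, edgeR with the composition term 12 higher and 12 lower (1311 at an unadjusted p under 0.05), and edgeR with a replicate block 0 (590 at an unadjusted p under 0.05). The 5 were named after their values were seen. Mp3g09180 stood at 20.5 ± 2.54 against 6.44 ± 1.44 CPM in WT, Mp3g09210 at 15.6 ± 5.79 against 1.71 ± 0.248, and Mp3g09230 at 5.56 ± 1.80 against 0.979 ± 0.289. All 3 were also higher in Mpvih than in WT, by 1.38, 3.5 and 2.69 on the log2 scale. Mp1g23900 stood at 94.6 ± 55.3 against 4.33 ± 1.69 CPM and Mp1g04100 at 171 ± 63.7 against 24.2 ± 10.1 CPM. For the 2446 genes of Mpvih against WT, the median absolute log2 difference was 1.26 in Mpvih and 0.214 in amiR-MpDELLA Mpvih, and 4 of them were called in the latter. The median 95% interval of that difference reached 0.614 to each side before adjustment, and larger differences than that also went uncalled, as for MpLUX and MpCNL1; the smallest called was 1.67. The count of 5 fell to 0 without WT replicate 2 or WT replicate 3, to 3 without Mpvih line 2 replicate 1, amiR line 1 replicate 3 or amiR line 2 replicate 2, and rose to 10 without amiR line 2 replicate 1.

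**Figure D3:**
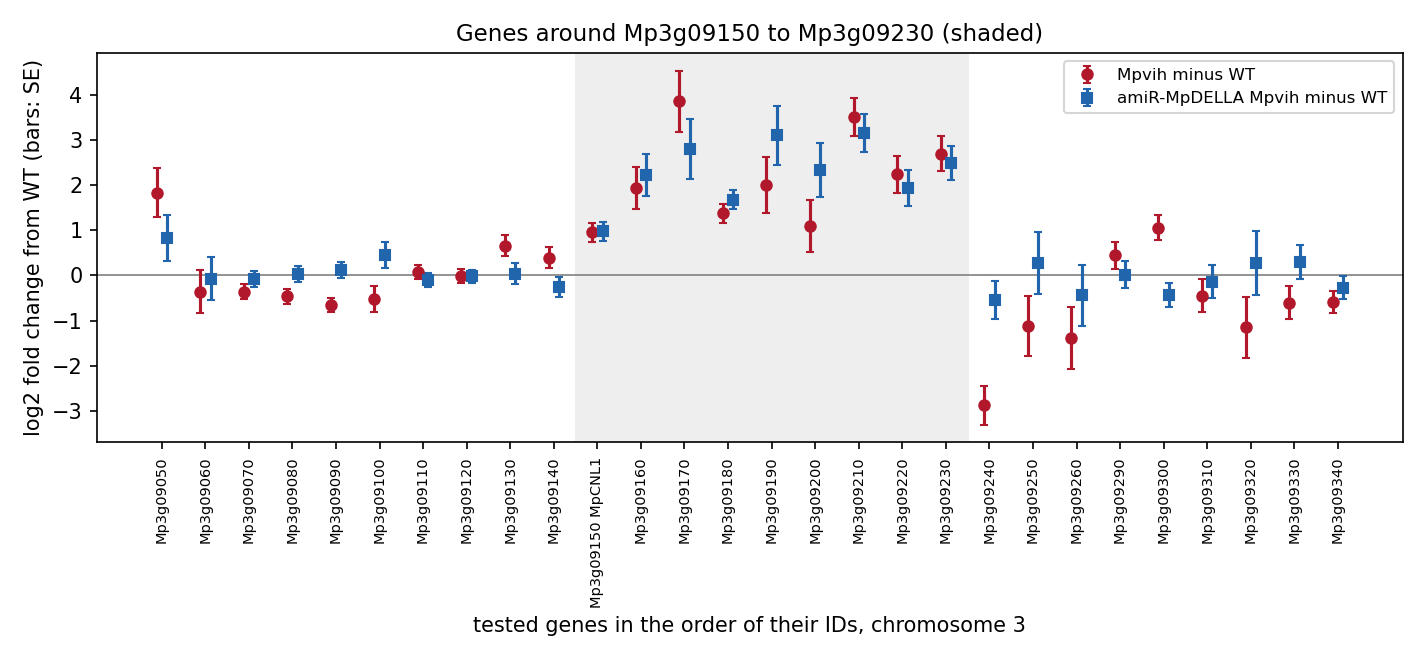
Log2 fold change from WT (vertical axis; bars are the standard error of the fit) of 28 tested genes in the order of their IDs on chromosome 3 (horizontal axis), for Mpvih (red circles) and amiR-MpDELLA Mpvih (blue squares). The 9 shaded genes, from MpCNL1 (Mp3g09150) to Mp3g09230, lay above WT in both, with amiR-MpDELLA Mpvih between 0.98 and 3.16; the shading was set after the values were seen.

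Genes linked to the sex chromosomes were read in each library because all plants were labelled as the female accession. Genes with U-linked IDs took 1745 to 2513 CPM, and 31 to 33 of the 48 had at least 10 counts in each library. Of the 33 tested, 2 rose and 1 fell in Mpvih against WT, and 4 rose and 5 fell in amiR-MpDELLA Mpvih against Mpvih. Camera gave adjusted p of 0.51 for both, and fry's directional adjusted p was 0.32 and 0.36. Fry's adjusted p for changes in either direction was 0.073 and 0.018, the latter in a comparison that called 38.1% of all tested genes. Genes with V-linked IDs took 79.5 to 689 CPM, and 4 to 9 of 146 had at least 10 counts. Of the 8 tested, 0 were called in Mpvih against WT, with the same result adjusted over the list alone, and 1 fell in amiR-MpDELLA Mpvih against Mpvih; camera gave adjusted p of 0.98 and 0.51.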

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

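The tests of sequencing depth, of residual RNA, of Mpvih against WT without the 4 libraries, of exchanged labels and of the MpGRAS6 level were chosen only after the results they bear on had been seen.

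Signals outside the comparisons drew attention in 2 places. Mp2g00015a, an ID with a letter suffix and no match in the reference, took 2071 counts in the lowest library and 71659 in the highest, amiR line 2 replicate 3, above the highest WT library (32467). The 775 suffixed IDs together took 0.0169% to 0.478% of the counts. MpVg01240, a V-linked ID in plants labelled female, took 355 to 9547 counts, with the highest value again in amiR line 2 replicate 3 and 8173 in the highest WT library. Both IDs were also lowest in the same library, Mpvih line 2 replicate 1, so they may not be separate signals. Without MpVg01240, V-linked IDs took 24.0 to 112 CPM. A single Mpvih line stood on the other side of WT for Mp1g23900: the 3 libraries of line 1 (mean 34 CPM) lay above all WT libraries (4.33 CPM) and the 3 of line 2 (2.06 CPM) below them, a difference of -4.02 on the log2 scale between line 2 and line 1 with an adjusted p of 0.096 in edgeR, which did not pass. The gene was picked after its values were seen.

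In composition, 4 libraries stood apart: WT replicate 1, amiR line 1 replicate 1, and amiR line 2 replicates 2 and 3. A term for them called 6018 genes, 2865 higher and 3153 lower, which describes how far they differ and is no independent test, since the same counts picked them. The tables argue against 2 technical causes. For sequencing depth, 0 of the 4 totals lay outside the range of the other 11. For a few abundant genes, the term still called 5967 genes without the 50 most abundant genes. That count decides little, because the trimmed mean already sets extreme genes aside. The TMM factors could have moved, but without those 50 genes the 4 stayed at 0.897 or lower, against at least 1.04 in the other 11. Residual RNA of suffixed IDs failed the test as written, which asked for all 4 shares to lie above the others: 3 of the 4 shares (0.235%, 0.318% and 0.478%) lay above the highest of the other libraries (0.123%) and 1, at 0.0774%, within their range. At no more than 0.478% of the counts, these IDs are too few to give TMM factors of 0.693 to 0.873 by themselves. As a sign of another difference between those libraries, the shares stay open. A difference in harvest, library batch or plant state stays open as well; the labels give none of these, and no biological explanation was tested.

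For the 2446 genes of Mpvih against WT, 100 regroupings of the 9 libraries were drawn, and 1 (the real split) gave as many; the highest of the others gave 2391. It is among 3 that kept the WT libraries together and exchanged only line labels, and the highest of the remaining regroupings was 239. A chance division of single libraries can thus be excluded. The regroupings treat libraries of a line as separate units, and 2 lines are too few to test chance between lines. Library composition as the whole cause is argued against by the fit without the 4 libraries, which called 2792 genes; of 2441 genes called before and tested in both, 1966 were shared in direction. For the 1015 genes shared by both Mpvih lines, 1 of 100 regroupings gave as many, and the others reached 983, again with the WT libraries kept together, or 0 without that. For single lines, 3 against 3 libraries make only 10 splits, too few for a share under 0.05: 1 of 10 gave as many as the 1406 genes of line 1 and as the 1886 genes of line 2, and the highest other split gave 0 in both cases. Between the Mpvih lines 10 of 10 splits gave at least the real count of 0 and the highest other gave 1, also too few splits. The loss of MpVIH, which the design names, stays open as the biological explanation.

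The third pattern is that amiR-MpDELLA Mpvih libraries lie close to WT. For the 4892 genes between amiR-MpDELLA Mpvih and Mpvih, 2 of 100 regroupings of the 12 libraries gave as many. The other one, with 4900, exchanged only line labels, and the rest reached 1008. As before, this excludes a chance division of single libraries but not chance between lines. For the 2237 genes shared by both amiR lines 1 of 100 did, and the others reached 2138 with genotypes kept and 0 otherwise. For the 5 genes between amiR-MpDELLA Mpvih and WT, 12 of 100 regroupings gave as many, so chance cannot be excluded for that count. The highest other gave 4666 and put 3 of the 4 libraries that stand apart in the group of 3, which points to that structure of the samples; without the 4 libraries the count was 2. Likewise, 10 of 10 splits of the amiR libraries gave at least the real count of 0 between lines, too few splits, and the highest other, 3552, set the 3 low-factor amiR libraries against the remaining 3. Libraries of plants like the WT of this series under an amiR-MpDELLA Mpvih label are argued against by neighbouring genes on chromosome 3. These were chosen as the fullest window of 10 with all libraries of Mpvih and of 1 amiR line on the same side of 2 WT libraries, and read in the other amiR line against the third WT library. In all 6 rotations the window lay between Mp3g09150 and Mp3g09240, and the median log2 difference of its 7 or 10 genes was between 1.26 and 2 in the chosen direction. On that side lay 7 of 7 or 9 of 10 genes, and within a rotation no library was used in both steps. The 6 rotations exchange the same libraries and return the same segment, whose separation from WT had been seen before. They are therefore not separate tests. A lower MpGRAS6 transcript level as the route stays open: the difference was -0.33 with a 95% interval from -0.67 to 0.01. With the composition term it was -0.29 (adjusted p = 0.25). Without the 4 libraries it was -0.49, but amiR line 2 is then replicate 1 alone, so nothing is concluded from that fit. An artificial microRNA may also act on translation, which RNA counts do not show, and plants that carry a working MpVIH were not excluded.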

How the results depend on the processing

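The composition term and the fit without the 4 libraries were chosen after seeing the data; the other alternatives were planned. For Mpvih against WT and amiR-MpDELLA Mpvih against Mpvih, counts stayed within 1.5 times the reported 2446 and 4892 under most alternatives. Those that kept every library of the compared groups and set no fold threshold gave 1865 to 3440 and 4173 to 5637. Of the 2446 genes, 2363 were shared with the composition term and 2439 with DESeq2. Of the 4892, only 3281 were shared in direction with the composition term, so a similar count there does not mean the same genes. Requiring a log2 fold change of at least 1 gave 1525 and 2223, and 1309 for both amiR lines, by construction. DESeq2 gave 123 genes for amiR-MpDELLA Mpvih against WT, 2347 for Mpvih line 1, 1665 for both Mpvih lines, 142 between Mpvih lines and 4 between amiR lines. Fitting only the groups compared gave 0, 923 (line 1), 1212 (line 2), 576 (both Mpvih lines) and 19 (between Mpvih lines), with fewer libraries in the fit. The composition term gave 24, 2475, 3030, 1742 and 54 for the same results, and the fit without the 4 libraries 2 for amiR-MpDELLA Mpvih against WT, 28 between Mpvih lines and 797 for both amiR lines. The count for both amiR lines in that fit rests on replicate 1 alone for amiR line 2, so nothing is concluded from it. With the composition term, which keeps all libraries, both amiR lines shared 2102. With 3 genotype means amiR-MpDELLA Mpvih against WT gave 3. Apart from the settings whose construction is named, the cause was not tested. The share of higher genes among those called in Mpvih against WT was 38.0%, against 36.4% with DESeq2 size factors, 35.2% with a replicate block, 42.1% with DESeq2, 44.1% without the 4 libraries and 45.2% with the composition term (1556 higher against 930). In amiR-MpDELLA Mpvih against Mpvih it was 53.4%, and 52.7% to 55.4% in these settings.

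Replicate numbers did not pair the libraries: same-numbered deviations had a mean r of -0.0558 (from -0.740 to 0.697; other numbers 0.0277), and 2 of 15 libraries were closest to their own number. With a replicate block Mpvih against WT gave 1865 genes, amiR-MpDELLA Mpvih against Mpvih 4200, and amiR-MpDELLA Mpvih against WT 0. Genes with the opposite sign in the amiR lines were 94.7%, and 97.3% chosen in line 2, 99.4% with shared Mpvih libraries. The 2 called tests of the terpene synthase list were 0 with an estimated correlation.

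Leaving out 1 library gave 1577 to 2856 genes for Mpvih against WT, 792 to 1728 for line 1 (792 and 870 without WT replicates 2 and 3, 821 and 860 without line 1 replicates 2 and 3), 907 to 2191 for line 2 (1245, 1248 and 1215 without WT replicates 1 to 3, 1034 and 907 without line 2 replicates 1 and 3), and 607 to 1226 for both Mpvih lines (607 and 634 without WT replicates 2 and 3, 617 without line 1 replicate 3, 652 without line 2 replicate 1). It gave 3779 to 5972 for amiR-MpDELLA Mpvih against Mpvih, 1374 to 2635 for both amiR lines, 0 to 10 for amiR-MpDELLA Mpvih against WT, 0 to 5 between Mpvih lines (5 without line 1 replicate 3), 0 between amiR lines, and 91.3% to 97.6% for the share of opposite signs. For named genes, 998 of 1050 alternative values kept direction and side of the threshold, 30 lost the call, 9 gained it, and 13 changed sign, none of them called before or after. For MpAOS1 in amiR-MpDELLA Mpvih against Mpvih these were -0.0415 with the composition term and -0.116 without the 4 libraries. For MpRSL1 they were 0.176 and 0.179 in that comparison, and in Mpvih against WT -0.176, -0.189, -0.192 without WT replicate 1 and -0.0139 without Mpvih line 2 replicate 3 (up to 0.351, without WT replicate 2). For MpCNL1 in amiR-MpDELLA Mpvih against Mpvih they were -0.00554, -0.134, -0.0472 without Mpvih line 1 replicate 3, -0.0390 without Mpvih line 2 replicate 2 and -0.0177 without amiR line 2 replicate 2 (up to 0.100007, without amiR line 2 replicate 1). Depth limits genes with few counts, such as MpMTPSL12 with 29 counts over the WT libraries.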

Other observations

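Further named genes moved between amiR-MpDELLA Mpvih and Mpvih, described here after their values were seen. MpICE2 (Mp4g04920) rose in Mpvih from 3.41 ± 0.0980 to 8.92 ± 2.45 CPM (log2 fold change 1.38, adjusted p = 0.041) and fell to 3.33 ± 1.59 CPM in amiR-MpDELLA Mpvih (-1.41, adjusted p = 0.0065). MpRAM (Mp8g01770), at low levels, fell by 2.06 in Mpvih (adjusted p = 0.034) and rose by 3.08 in amiR-MpDELLA Mpvih (adjusted p = 0.0010). MpBZIP11 (Mp2g23600) fell from 42.3 ± 3.05 to 31.3 ± 4.30 CPM in amiR-MpDELLA Mpvih (adjusted p = 0.0037). Of 35 named genes called in this comparison and tested in both fits that take account of the 4 libraries that stand apart, 13 lost the call in both, 6 that rose (MpBZIP12, MpFIT2, MpRVE and MpMTPSL6, MpMTPSL10 and MpMTPSL11) and 7 that fell (MpKCS2, MpLD, MpPHD and the following). MpPIF (Mp3g17350), of the phytochrome-interacting factors, fell by 0.63 (adjusted p = 0.029), MpKAN (Mp3g04970) by 0.69, MpWIP (Mp1g09500) by 0.62 and MpWOX (Mp1g11660) by 0.57. With the composition term the differences were -0.3, -0.37, -0.43 and -0.24 (adjusted p of 0.18, 0.12, 0.057 and 0.24), and without the 4 libraries -0.46, -0.38, -0.43 and -0.31 (0.054, 0.18, 0.11 and 0.15). Each of these 4 differences was smaller and kept its sign, and MpWIP was not among the genes called for the composition term itself. Among genes that rose, MpFIT2 kept most of its difference, 0.53 against 0.46 with the composition term and 0.43 without the 4 libraries. In the same order MpBZIP12 went from 0.8 to 0.42 and 0.31, and MpRVE from 0.94 to 0.36 and 0.25. In the fit with the composition term, the 4 libraries had lower MpCKI1 (3.00-fold), MpRAV (2.56-fold) and MpE(z)1 (2.39-fold, a subunit of the Polycomb complex that methylates histone H3), and higher MpRVE (1.93-fold, named for a clock regulator) and MpAOS2 (1.71-fold).

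A few unnamed genes with large changes in Mpvih were picked after their values were seen. Mp8g18650 had 10640 counts over the WT libraries, 7 over the Mpvih libraries and 10815 over the amiR libraries, with 299 ± 302, 0.0885 ± 0.134 and 155 ± 108 CPM. The highest WT library was WT replicate 1, among the 4 libraries that stand apart, at 648 CPM against 129 and 122 CPM in the other WT libraries, and the 3 amiR libraries among the 4 were also the highest of theirs. Its neighbours Mp8g18610, Mp8g18620 and Mp8g18640 had 516, 1501 and 461 counts in WT and 0 in all 6 Mpvih libraries; WT replicate 1 was the highest for each, with 42.4 CPM of Mp8g18610 against 1.52 and 3.43 CPM. Among genes that rose, Mp2g22430 had 0 counts in WT, 4987 in Mpvih and 1 in amiR-MpDELLA Mpvih, at 147 CPM in line 1 and 2.42 CPM in line 2. Mp3g18400 had 2, 936 and 67 counts. Mp6g21120 also rose, from 19 counts in WT to 1224 in Mpvih and 7 in amiR-MpDELLA Mpvih.

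Of the tests below, the search for a segment was chosen after the genes had been seen; those of neighbouring genes and of a shared background were set before their results were seen, the latter without the 2 genes that prompted it. The hypothesis that called genes cluster along the chromosomes was tested by counting adjacent tested genes called in the same direction in Mpvih against WT. There were 429 such pairs, against a median of 243.5 and a maximum of 300 in 10000 shuffles of gene positions (one-sided permutation p = 1e-04, the smallest they can give). The longest run held 7 lower genes, Mp3g18500 to Mp3g18580, with a median log2 fold change of -1.40 in Mpvih and 1.69 in amiR-MpDELLA Mpvih against Mpvih. A run of 6, Mp3g24140 to Mp3g24210, had medians of -4.45 and 3.11, and the run of 5 that holds Mp8g18650 had -10.71 and 9.18, fitted values that depend on the prior count. Tandem copies that share reads, or that share control, may both give such runs; without sequences these could not be parted.

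Genes that stayed apart from WT in all 12 libraries of the Mpvih background may mark a linked genomic segment that differs between the WT stock and that background. Of the 12850 tested genes 120 (0.934%) had all 12 libraries on the same side of the 3 WT libraries, where chance gives 0.440%. The fullest windows of 10 neighbours, which lie between Mp3g09140 and Mp3g09240, held 7 of them, against at most 5 in 10000 shuffles (one-sided permutation p = 1e-04, the smallest they can give), and the next window elsewhere held 2. In the 9 tested genes from Mp3g09150 to Mp3g09230 the median log2 difference from WT was 2 in Mpvih, where 8 were called, and 2.34 in amiR-MpDELLA Mpvih, where 3 were called, or 6 with the composition term. Between the genotypes 1 of the 9 was called (Mp3g09200, 1.25, adjusted p = 0.039), and the members went both ways around a median of 0.03. That they stayed apart from WT in the amiR lines follows from how they were chosen, and a difference from other genes was not tested. The search fits a segment but does not separate it from shared control of neighbouring genes that MpDELLA does not affect, and reads of the segment were not analysed here. The word Gemma in the titles divides the 3 WT libraries from the other 12 in the same way. If it marks other starting material, that cannot be told apart from a segment either.

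Mp1g23900 and Mp1g04100 were higher in Mpvih line 1 (34 and 160 CPM) and in both amiR lines (84.6 and 190, and 105 and 152) than in WT (4.33 and 24.2) and line 2 (2.06 and 45.7). A candidate explanation is that the amiR-MpDELLA Mpvih lines share a background with Mpvih line 1. Among other genes apart from WT and from the other line in line 1 alone, in the fit with the composition term, 1 of 22 kept at least 50% of its log2 change in the amiR lines, against 0 of 16 for line 2 (Fisher's exact test, two-sided p = 1). So few genes decide nothing, and a return of most genes towards WT in the amiR lines would hide such a share, so the explanation stays open.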
